A study of Mus musculus with 39 samples.

How the data were processed

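RNA was sequenced from 3 parts of the gut of 13 mice, 6 of the inbred strain BALB/cJ and 7 of the inbred strain C57BL/6J. Each mouse gave 1 library from the colon, 1 from the ileum and 1 from a sample labelled duodenum/jejunum, 39 libraries in 6 groups of 6 or 7. The labels give strain, tissue and a mouse number and no sex, age, batch or time of collection. A number in both strains stands for different animals, and the same strain and number in the 3 tissues for 1 animal. The groups were compared as unpaired within a tissue.

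Per the labels, RNA was extracted with a PureLink kit and made into TruSeq total RNA libraries after ribosomal RNA was depleted with RiboZero. The authors' notes name kallisto 0.44.0 for quantification and the mouse genome build GRCm38. The transcript annotation behind the gene names is not given in the sources used here. The deposited tables, 1 per tissue, hold log2(TPM + 1) values for 34600 entries with 34598 distinct names. Turned back to TPM, each library sums to between 979558 and 996230, and 14557 to 16186 entries reach 1 TPM. TPM keeps no record of the number of reads, so the depth behind each value is unknown, no counting interval can be given, and precision rests on the spread between mice. Per tissue, 26 names had been turned into dates. These entries held at most 0.127% of TPM in any colon library, 0.218% in any ileum library and 0.238% in any duodenum/jejunum library, and were not named. No column belonged to another sample (0 columns), and no pair of libraries was identical.

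Strains were compared within each tissue with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean, on log2(TPM + 1). Genes with at least 1 TPM in at least 6 of the 13 libraries were tested. All tests are 2-sided unless stated, p-values were adjusted by the Benjamini-Hochberg method over all genes tested in the tissue, and genes with an adjusted p under 0.05 were called. Fold changes from the fit are differences of log2(TPM + 1), which are smaller than ratios of TPM for genes near the pseudocount of 1, so ratios of mean TPM are given as folds. For sums and scores per library, exact permutation tests over the 1716 splits of 13 libraries into 6 and 7 were used, adjusted over 48 measures per tissue. Means are of TPM over the libraries of a group with the standard deviation (SD).

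The plan was written for counts and foresaw this test in case the tables held TPM. It joined the tissues only for unscaled counts, so tissues are compared here by level, without a test. The test of whether a strain difference differs between tissues is a departure from the plan. It was a limma fit of all 39 libraries in which each tissue had its own mean, chosen once the unit was known.

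Gene lists for cell types, pathways and gut regions, 40 in all with 1 used as a check of the strain labels, were fixed before the data were examined. Lists with at least 5 tested members were tested against all other genes with camera in limma, with a preset correlation of 0.01 between genes and again with the correlation estimated per list. That made 39 lists in the colon and 37 in each part of the small intestine. For each list the number of members called is given over all genes tested and adjusted over the list alone.

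The genes named were chosen by a rule set with the lists. It takes the label check genes, and in each tissue the 6 called genes with the largest change in each direction that have a mean of at least 5 TPM and no overlap between the strains, leaving out predicted genes, pseudogene and mitochondrial symbols, clones and antigen receptor segments. It adds up to 4 called members per list by smallest adjusted p, the 8 genes with the smallest adjusted p for a difference between tissues, 3 markers per region list, and 5 genes per direction called in all 3 tissues. A few genes that the rule names are not reported here. Symbols were matched to GENCODE M21 for coordinates on GRCm38: 31787 matched once, 43 more than once and 2768 not at all. Reads of near-identical paralogs and of pseudogenes can be assigned to 1 copy or another, which limits the values of single members of the alpha-defensin, Sprr2a, Mptx and H2 class I families and of processed copies such as Rps3a2 and Eno1b. Whether variants of BALB/cJ against the C57BL/6J reference change the values of single genes or the sums of families was not tested. This includes the alpha-defensin, Sprr2a, Mptx, H2 and immunoglobulin families.

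The same code was tested on simulated data with the mean and spread of these tables and changes put into 200 genes. In the colon it called 73.1% of changes of 0.5 on the log2 scale, 91.0% of changes of 1 and 97.0% of changes of 2, and 5.43% of its calls were false. For the ileum the shares were 40.3%, 80.6% and 100.0% with 6.37% false, and for the duodenum/jejunum 34.3%, 80.6% and 97.0% with 4.08% false. It called 93.5% of changes of 2 put into 1 tissue alone in the test between tissues. For lists it called the shifted list in each tissue, and no list in the data without that shift. The simulated genes were drawn independently, so this cannot show how the list tests behave when members vary together.

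Alternatives were median-of-ratios size factors (RLE), a pseudocount of 0.1, no filter on low values, a fold threshold, the mouse number as a block, a B cell score as a covariate, an estimated correlation and the fry test for lists. All 39 libraries in 1 fit was planned for unscaled counts and run on TPM once the unit was known. Others were chosen after the data were seen: leaving out libraries of C57BL/6J mouse 2, leaving out the ileum library of BALB/cJ mouse 2, leaving out 3 mice with Y-linked transcripts, protein-coding genes alone, and TPM rescaled without the alpha-defensins. Tables were read with Python 3.11.15 and pandas 2.3.3, permutations used numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.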

Results

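Levels in TPM were compared between BALB/cJ (n = 6 mice) and C57BL/6J (n = 7 mice) in the colon, the ileum and the duodenum/jejunum. These n hold for every mean below, and each ± is an SD unless called SE.

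The strain labels were checked first with genes whose alleles are known to differ. H2-Ea-ps, an MHC class II gene disrupted in C57BL/6 mice, reached 122 ± 26 TPM in the colon, 395 ± 67.6 in the ileum and 141 ± 40.8 in the duodenum/jejunum of BALB/cJ, with maxima of 0.246, 0.233 and 0.381 TPM among C57BL/6J libraries. Pla2g2a, a secreted phospholipase gene with a defective allele in C57BL/6 mice, was 15.1-fold, 38.2-fold and 45.7-fold higher in BALB/cJ (adjusted p in limma 2.7e-10, 6.2e-07 and 8.2e-12). Ighg2c, the C57BL/6-type IgG2 constant gene, was not called in the colon (2.13 against 0.958 TPM, adjusted p 0.141) or the duodenum/jejunum (1.08 against 1.27, 0.754), and in the ileum it was higher in BALB/cJ (4.41 ± 1.64 against 1.71 ± 0.872 TPM, 0.0074, or 0.111 with the B cell score as a covariate). Nnt, which carries a deletion in C57BL/6J, did not differ in any tissue (11.9 against 10.6, 14.5 against 11.1 and 14.9 against 12.1 TPM; adjusted p 0.315, 0.137 and 0.349), and gene totals do not show which exons were read. Every library fell on its labelled side for H2-Ea-ps and Pla2g2a. Ighg2c and Nnt did not bear out the labels, and the ileum difference of Ighg2c was opposite to what its allele predicts. The cause was not tested.

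Of the region markers, 13 of 13 for the colon, 8 of 12 for the ileum and 14 of 16 for the duodenum and jejunum had their highest mean in their own tissue. The 4 ileal markers that did not were Gip, Clec2h, Ces1f and Defa24, and the others were Slc40a1 and Ces1d. The 3 shown per list are those with the largest contrast. Car1, a carbonic anhydrase of the large bowel, reached 3074 ± 779 TPM in BALB/cJ and 4330 ± 1491 in C57BL/6J colon. Aqp8 was at 461 and 316 TPM and Hoxb13 at 123 and 112. The ileal bile acid binding gene Fabp6 was at 6762 ± 2205 and 4454 ± 2405 TPM in the ileum. Slc51b was at 350 and 333 TPM and Fgf15 at 55.4 and 19.4. Tmprss15, which encodes enteropeptidase, was at 47.2 and 35.6 TPM in the duodenum/jejunum and Fabp1 at 7686 and 5505. The gastric and proximal duodenal gene Gkn3 ranged from 1.54 to 716 TPM among BALB/cJ and from 7.62 to 651 TPM among C57BL/6J libraries. In C57BL/6J mouse 2 the library labelled ileum held 22.1 TPM of Fabp6 and 51.2 of Tmprss15, and the library labelled duodenum/jejunum 6111 of Fabp6 and 39.2 of Tmprss15. Both libraries were kept in the main comparisons, and results that end without them are named.

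**Figure D1:**
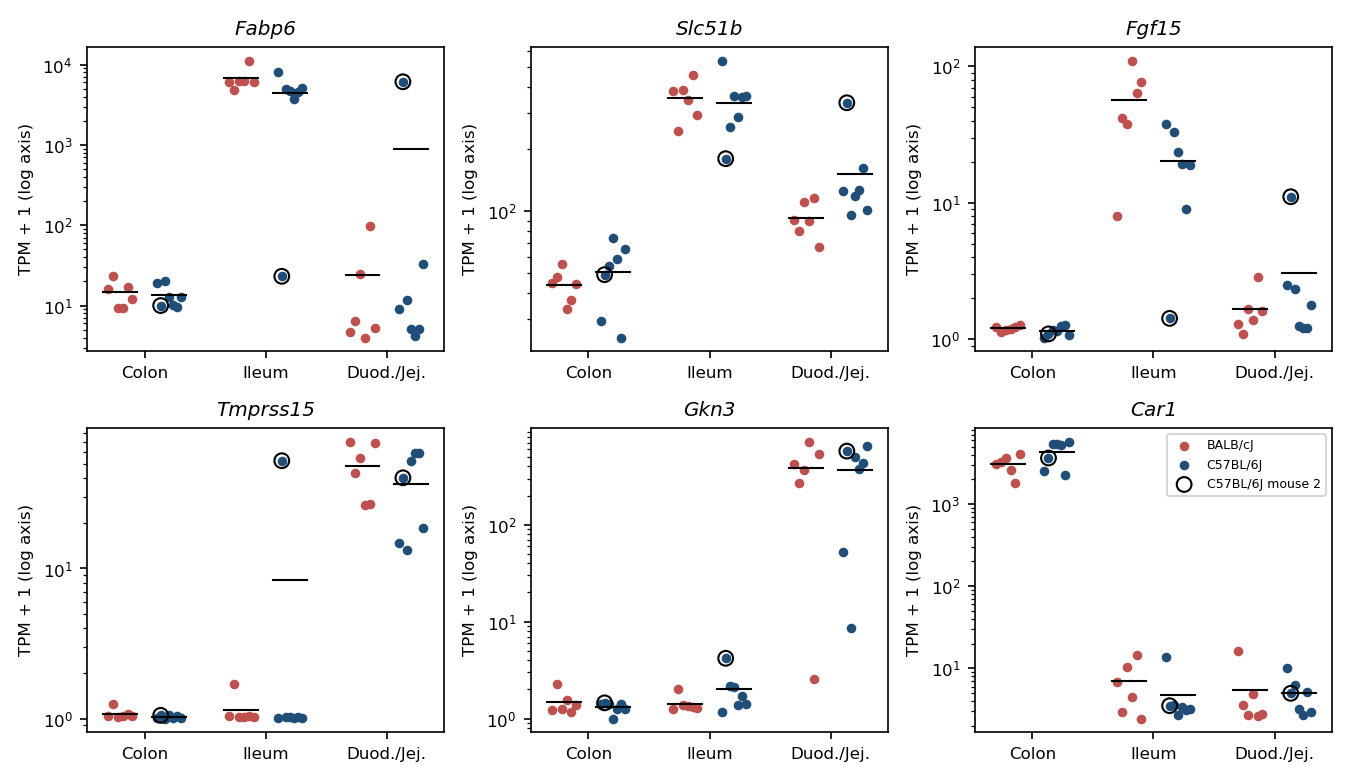
Levels of region markers in each library by tissue and strain, on a log axis of TPM + 1. Points are libraries and lines are arithmetic means.

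In the colon, a lactoperoxidase gene of mucosal defence was among the largest strain differences: Lpo reached 336 ± 28.3 TPM in BALB/cJ and 13.7 ± 1.75 in C57BL/6J, 24.6-fold higher (log2 change 4.53 ± 0.08 SE, adjusted p 1.5e-14). A pair of related genes of the neurexophilin and PC-esterase family went in opposite directions. Nxpe5 was at 136 ± 12.1 against 1.52 ± 0.411 TPM and Nxpe4 at 1.52 ± 0.144 against 48.5 ± 9.68 (adjusted p 9.1e-15 and 1.8e-12). Of 2 mucosal pentraxin genes, Mptx2 was higher in BALB/cJ (44.1 ± 9.64 against 0.866 ± 0.365 TPM) and Mptx1 lower (548 ± 142 against 2832 ± 1325, adjusted p 3.4e-05), and their sum was lower (592 ± 151 against 2833 ± 1325, exact permutation p 0.0017, adjusted 0.0044). Gbp2b, a guanylate-binding protein gene induced by interferon, was 29.1-fold higher. The sialyltransferase gene St3gal4 was 9.77-fold lower (23.5 ± 4.44 against 230 ± 32.5 TPM), and Gvin1, Cep85, Chd9 and Pnp2 were lower by 28.9-fold, 15.1-fold, 14.9-fold and 12.6-fold. Rps3a2 and Eno1b, listed at 283 ± 22.6 and 233 ± 27.8 TPM in BALB/cJ and at 1.69 and 1.76 in C57BL/6J, resemble copies of highly expressed genes with which they can share reads.

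On GRCm38, Lpo lies on chromosome 11 from 87806428 to 87828289 and Nxpe5 on chromosome 5 from 138225898 to 138253363. Nxpe4 and St3gal4 lie on chromosome 9 from 48162023 to 48400025 and from 35046576 to 35119268. Mptx1 and Mptx2 lie on chromosome 1 from 174330518 to 174332873 and from 173274382 to 173277777. Chd9 lies on chromosome 8 from 90828352 to 91054516 and Pla2g2a on chromosome 4 from 138831857 to 138835186. Over all genes, limma called 3986 of 15769 in the colon (25.3%), 2286 higher and 1700 lower in BALB/cJ, of which 413 and 180 changed by at least 2-fold. The strains did not overlap for 1807 of all genes tested, called or not, where chance gives 0.117% of genes. With the B cell score as a covariate, which itself separates the strains, 479 genes were called (280 higher, 199 lower). Of 98 called colon genes picked by the naming rules 58 ended, with a change as large or larger but less precise in 17 (Ube2c, Lss and Adipoq among them), a smaller one in 31 (much smaller for Insig1 and Myh11, hardly so for Trpm5, at -0.81 against -0.85) and the other sign in 10. Genes that kept their call include Rtp4, H2-K1, Sprr2a2, Avil and Ephb2.

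Interferon-stimulated genes were higher in the BALB/cJ colon. Rtp4 was at 66.6 ± 13.2 against 11.8 ± 2.14 TPM, Ifit3b was 3.98-fold higher, Ifi44l was at 4.35 ± 1.54 against 0.0131 ± 0.0225, and Trim30d was 9.20-fold lower. Of 62 such genes tested, 50 were higher, 2 lower and 10 not called (54 and 2 adjusted over the list alone). As a list they ranked above other genes (camera adjusted p 2.5e-26), with an adjusted p of 0.205 when the correlation was estimated.

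Genes of lymphoid and myeloid cells were also higher in the BALB/cJ colon, together with genes of fat and blood. Of B cell and germinal centre genes, Ighd was at 8.98 ± 1.63 against 2.81 ± 0.370 TPM, Cd79a was 2.79-fold and Fcrl1 3.52-fold higher, and 19 of 23 were higher, 1 lower and 3 not called (20 and 1 adjusted over the list alone; camera adjusted p 1.9e-09, and p 0.317 with estimated correlation). The lower one, Rgs13 (3.70 against 7.28 TPM), is also a tuft cell gene. Of T cell genes 15 of 18 were higher and 3 not called (16 adjusted over the list alone), with Trbc2 2.23-fold, Cd27 1.85-fold and Cd3d 1.98-fold higher (p 1.7e-06, and 0.205 with estimated correlation). Of macrophage and dendritic cell genes 15 of 26 were higher and 11 not called (16 adjusted over the list alone), with Lyz2 at 308 ± 66.7 against 132 ± 32.6 TPM, Mpeg1 1.99-fold and Ccr7 3.63-fold higher (p 1.5e-05, and 0.458 with estimated correlation). Of plasma cell genes 7 of 19 were higher and 12 not called (9 adjusted over the list alone), with Ighm 2.58-fold and Pou2af1 2.56-fold higher (p 0.0019, and 0.458 with estimated correlation). Adipocyte genes were higher in 8 of 11 with 3 not called (8 adjusted over the list alone), with Fabp4 at 68.4 ± 26.1 against 27.1 ± 3.63 TPM and Adipoq 3.01-fold higher (p 0.0022, and 0.458 with estimated correlation). Haemoglobin Hba-a1 was at 94.4 ± 36.5 against 36 ± 9.79 TPM, and 3 of 5 erythroid genes were higher (4 adjusted over the list alone; p 0.0998). Stromal and endothelial genes were higher in 11 of 18 with 7 not called (14 adjusted over the list alone), among them Col3a1 (1116 ± 207 against 697 ± 161 TPM), Madcam1 and Pdgfrb (p 0.00052, and 0.458 with estimated correlation). A mean B cell score was 2.90 ± 0.167 against 2.02 ± 0.205 on the log2 scale (exact permutation p 0.000583, the smallest the splits can give, adjusted 0.002), and the score of pancreatic genes, high in the BALB/cJ mice 3 and 5 at 6.85 and 6.04, differed too (5.10 ± 1.07 against 4.27 ± 0.0802). With the B cell score as a covariate, none of the genes named here as higher was called. The log2 change fell from 0.72 to 0.04 for Cd3d and from 0.94 to 0.07 for Mpeg1, but was 2.22 ± 0.97 SE against 1.45 ± 0.35 for Adipoq, 1.20 against 1.24 for Fabp4 and 1.66 against 1.33 for Hba-a1. For these last 3 genes the error was wider and the change about as large or larger. Ighd, Cd79a and Fcrl1 are members of the score, which shrinks their change by construction.

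Antigen presentation and complement genes changed by member. H2-K1, a class I molecule, was at 200 ± 12.7 against 626 ± 56.8 TPM, while H2-Q6 was 7.38-fold, H2-Q10 4.47-fold and H2-Q4 3.19-fold higher. Of 28 class I presentation genes, 15 were higher, 2 lower and 11 not called (16 and 2 adjusted over the list alone; camera adjusted p 0.00054, and p 0.458 with estimated correlation). The sum over H2 class I genes did not pass (1490 ± 103 against 1623 ± 166 TPM, exact permutation p 0.121). Of 14 class II presentation genes, 7 were higher, 1 lower and 6 not called (9 and 1 adjusted over the list alone), with H2-DMb2 2.82-fold higher and Ctss 1.24-fold lower (p 0.0022, and 0.458 with estimated correlation). Of 34 complement genes, 19 were higher, 3 lower and 12 not called (22 and 3 adjusted over the list alone), with C3 at 53.8 ± 7.85 against 26.1 ± 4.91 TPM and C1rb at 3.25 against 0.0320 (p 0.00017, and 0.458 with estimated correlation).

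Proliferation and tuft cell genes were lower in the BALB/cJ colon and cholesterol synthesis genes higher. Of 25 proliferation genes, 17 were lower and 8 not called (18 adjusted over the list alone), such as Ube2c at 29.2 ± 4.97 against 47.2 ± 5.77 TPM and Kif11, 1.63-fold lower (camera adjusted p 1.7e-06, and p 0.458 with estimated correlation). Of 14 stem cell genes Ephb2 (1.80-fold) and Smoc2 (1.33-fold) were lower and 12 were not called (2 adjusted over the list alone; p 0.0058, and 0.401 with estimated correlation). Tuft cells, chemosensory cells of the epithelium, were read by 15 genes, of which 8 were lower, 1 higher and 6 not called (8 and 2 adjusted over the list alone), with Avil 2.19-fold, Trpm5 1.97-fold and Dclk1 1.84-fold lower (p 0.0013, and 0.317 with estimated correlation). Of 24 cholesterol synthesis genes 17 were higher, 1 lower and 6 not called (18 and 1 adjusted over the list alone), with Insig1 at 162 ± 22 against 72.9 ± 18 TPM, Lss 1.77-fold and Nsdhl 1.64-fold higher (p 6.6e-06, and 0.458 with estimated correlation). Smooth muscle genes were lower in 5 of 16 with 11 not called (7 adjusted over the list alone), with Acta2 1.23-fold and Myh11 1.18-fold lower (p 0.0058, and 0.458 with estimated correlation). Genes of enteric neurons and glia were lower in 3 of 17 with 14 not called (2 adjusted over the list alone), with Sox10 1.80-fold and Uchl1 1.61-fold lower (p 0.012, and 0.474 with estimated correlation).

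Antimicrobial genes of the colon epithelium differed without a common direction. Sprr2a2, of a small proline-rich family, was at 811 ± 99.5 against 6731 ± 456 TPM and Sprr2a1 8.06-fold lower. Their sum with Sprr2a3 was 1528 ± 197 against 7807 ± 527 TPM (exact permutation p 0.000583, adjusted 0.002). Reg4 was 1.96-fold higher. Of 35 antimicrobial genes 8 were higher, 6 lower and 21 not called (10 and 6 adjusted over the list alone), and the list was not called (camera adjusted p 0.78). Paneth cell products other than defensins were higher in 7 of 11, lower in 2 and not called in 2 (7 and 2 adjusted over the list alone), with Mmp7 at 10.6 ± 4.28 against 1.80 ± 0.634 TPM and Guca2b, the uroguanylin gene expressed outside Paneth cells as well, 1.65-fold higher (camera adjusted p 0.0033, and p 0.205 with estimated correlation). Of 32 mucin glycosylation genes 3 were higher, 8 lower and 21 not called (3 and 8 adjusted over the list alone), with B3gnt3 2.17-fold and B3gnt6 1.80-fold lower and Chst4 1.47-fold higher, and the list was not called (p 0.0598). Goblet cell genes moved both ways, with Zg16 at 11690 ± 1108 against 7703 ± 1617 TPM, Muc1 2.36-fold higher and Agr2 1.23-fold lower, 6 higher, 5 lower and 10 not called of 21 (6 and 6 adjusted over the list alone).

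**Figure D2:**
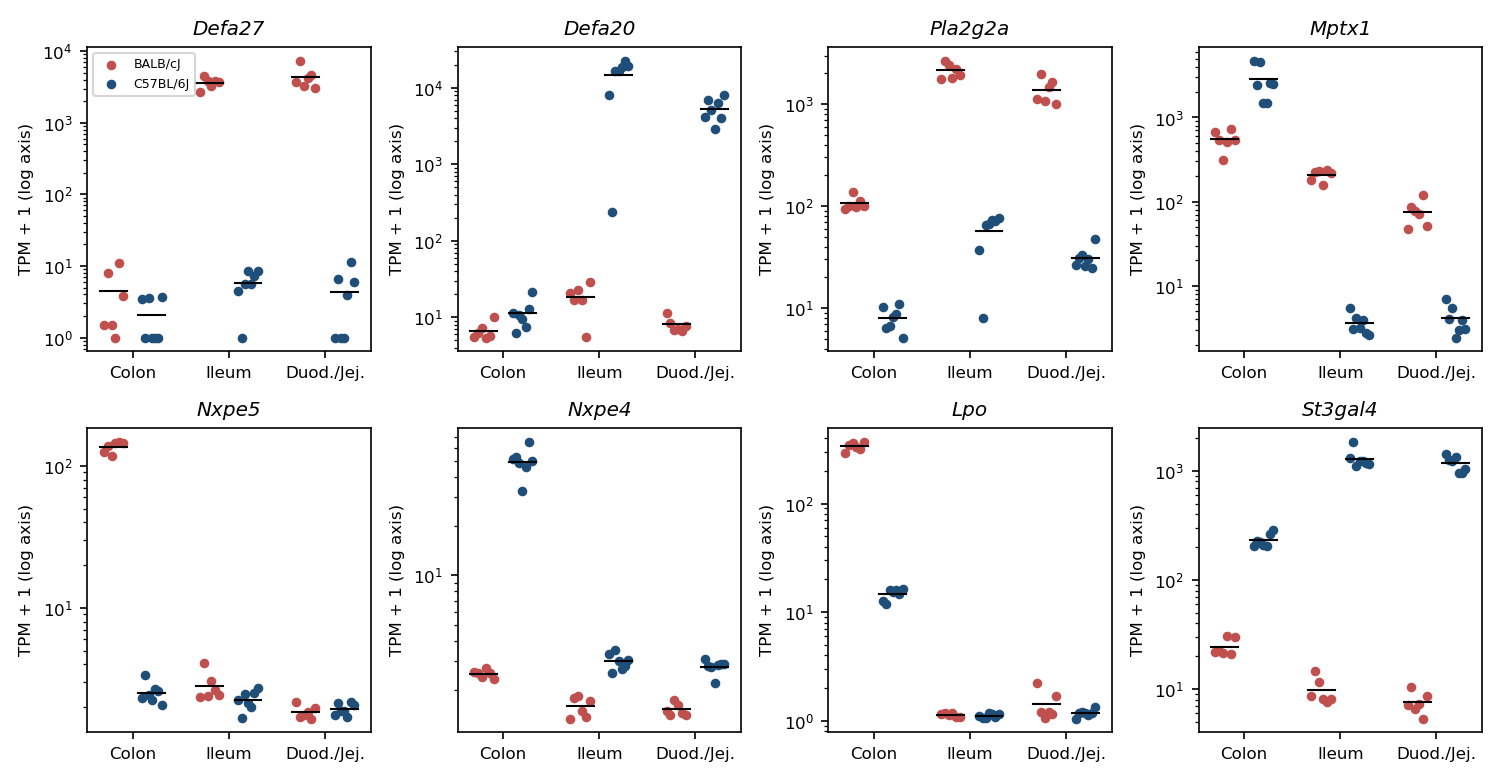
Levels of named genes in each library of each tissue, by strain, on a log axis of TPM + 1. Points are libraries and lines are arithmetic means.

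In the ileum, transcripts of alpha-defensins, antimicrobial peptides of Paneth cells, were assigned to different members in each strain. Defa27 reached 3635 ± 618 TPM in BALB/cJ and 4.83 ± 2.62 in C57BL/6J, 752-fold higher (adjusted p 3.4e-10). Defa20 was at 17.5 ± 7.76 against 14460 ± 7675 TPM, Defa21 at 0.952 ± 1.65 against 6291 ± 3330, Defa22 at 6.62 ± 3.60 against 4698 ± 2541 and Defa32 at 8.80 ± 7.83 against 8228 ± 4587 (adjusted p 6.3e-06, 5.2e-07, 6.3e-06 and 8.4e-05). Defa2 and Defa33 were listed at 0 in every BALB/cJ ileum library and at 3032 ± 1557 and 1708 ± 891 TPM in C57BL/6J. Of 20 alpha-defensins tested, 11 were lower in BALB/cJ, 1 higher and 8 not called (13 and 2 adjusted over the list alone; camera adjusted p 5.1e-13, and p 0.446 with estimated correlation). The sum over all Defa genes was 35800 ± 4888 against 81250 ± 41920 TPM (exact permutation p 0.0221, adjusted 0.0425), and 94120 ± 26860 in C57BL/6J without mouse 2 (exact permutation p 0.0022, the smallest those splits can give), whose library labelled ileum held 239 TPM of Defa20. Defa27 and Defa20 lie on chromosome 8 from 21315546 to 21316481 and from 21509258 to 21510237. Near-identical members can exchange reads, so in that respect the values of single members are less certain than the sum. Whether variants of BALB/cJ against the C57BL/6J reference change the sum was not tested.

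Other secreted products of Paneth cells and the epithelium also differed in the ileum. Pla2g2a was at 2142 ± 367 against 56.0 ± 25.2 TPM. Mptx1 was 80.1-fold higher in BALB/cJ (207 ± 31.2 against 2.58 ± 1.00 TPM, adjusted p 2.9e-12) and Mptx2 11.8-fold lower (61.3 ± 26.4 against 723 ± 428, 0.0075). Sprr2a2 was at 63.0 ± 27.1 against 2659 ± 817 TPM and Sprr2a1 38.9-fold lower, while Reg4 and Pla2g4c were 3.05-fold and 3.03-fold higher. Of 33 antimicrobial genes 3 were higher, 5 lower and 25 not called (3 and 5 adjusted over the list alone; camera adjusted p 2.3e-05, and p 0.446 with estimated correlation). St3gal4 was at 8.82 ± 2.75 against 1286 ± 249 TPM (146-fold lower) and B3gnt3 3.52-fold lower, while St3gal6 was 2.46-fold higher. Of 31 mucin glycosylation genes 1 was higher, 5 lower and 25 not called (1 and 5 adjusted over the list alone; p 0.00047, and 0.37 with estimated correlation). Muc3, a membrane mucin gene of enterocytes, was 2.18-fold and Muc4 3.33-fold lower. The histone gene Hist2h2aa2 was at 89.8 ± 28.8 against 7.14 ± 14.4 TPM.

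Over all genes, limma called 3169 of 15537 in the ileum (20.4%), 2677 higher and 492 lower in BALB/cJ, with 374 and 178 changed by at least 2-fold. Of all genes tested, 1525 were without overlap between strains, against the same chance share of 0.117% of genes. The median of all genes tested was higher by 0.17 on the log2 scale in BALB/cJ, so the direction of the calls depends on the scaling: with RLE size factors 1822 genes were called, 938 higher and 884 lower. Without C57BL/6J mouse 2 limma called 3642 (3038 higher, 604 lower), or 2270 with RLE (1163 higher, 1107 lower). The camera results below compare a list with other genes and so stand relative to that shift.

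Tuft cell genes were lower in the BALB/cJ ileum, with Avil at 1.83 ± 0.235 against 6.28 ± 1.58 TPM, Trpm5 3.48-fold and Sh2d6 12-fold lower. Of 14 tested, 7 were lower, 1 higher and 6 not called (7 and 1 adjusted over the list alone; camera adjusted p 2.8e-07, and p 0.446 with estimated correlation). Of 64 interferon-stimulated genes 7 were higher, 5 lower and 52 not called (7 and 5 adjusted over the list alone), with Gbp6 3.81-fold and Trim30d 3.95-fold lower and Samd9l 1.67-fold higher. The list ranked below other genes (p 0.00037, and 0.699 with estimated correlation), but only against the shift of all genes: its own median change was -0.02, its score 4.49 ± 0.206 against 4.52 ± 0.186 (exact permutation p 0.74) and its p with fry 0.988. Macrophage and dendritic cell genes were higher in 12 of 27 with 15 not called (17 higher and 1 lower adjusted over the list alone), with Siglech at 6.41 ± 2.20 against 1.13 ± 0.237 TPM, Ly6c2 3.86-fold and Cx3cr1 2.04-fold higher (p 0.002, and 0.994 with estimated correlation). Stromal and endothelial genes were higher in 11 of 18, lower in 1 and not called in 6 (15 and 1 adjusted over the list alone), with Pdgfra 1.89-fold and Kdr 1.77-fold higher (p 0.0265, and 0.994 with estimated correlation). B cell genes were higher in 9 of 26, lower in 1 and not called in 16 (16 and 1 adjusted over the list alone), with Ltb 2.07-fold and Fcer2a 1.78-fold higher (p 0.023, and 0.994 with estimated correlation, or 0.0698 without C57BL/6J mouse 2 and 0.07 without BALB/cJ mouse 2, the library with the highest B cell score of its strain). Hba-a1 was 3.04-fold higher, and the erythroid score was 3.93 ± 0.343 against 3.05 ± 0.216 on the log2 scale (exact permutation p 0.0012, adjusted 0.0062).

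The class II gene H2-Ab1 was at 402 ± 23.3 against 638 ± 104 TPM in the ileum and H2-DMb2 at 48.1 ± 6.56 against 14.9 ± 6.07, and H2-K1 was 2.90-fold lower. Of the remaining lists called in the ileum, type 2 immunity had 1 of 14 genes higher (Ccl11, 2.24-fold) and 3 lower, among them Siglecf at 0.514 ± 0.141 against 2.25 ± 1.45 TPM, with 10 not called (1 and 3 adjusted over the list alone; camera adjusted p 0.0265, and p 0.55 with estimated correlation). Pancreatic genes were lower in 2 of 7 with 5 not called (3 adjusted over the list alone), Rnase1 2.38-fold and Cela1 1.38-fold (p 0.0145, and 0.446 with estimated correlation). Colon region markers were lower in 1 of 8, Prdx6 by 1.71-fold, with 7 not called (1 higher and 3 lower adjusted over the list alone; p 0.023, and 0.446 with estimated correlation). Of 31 brush border genes none was called in either direction, by limma over all genes or adjusted over the list alone, and Fabp2 was at 8035 ± 3266 against 6717 ± 2079 TPM, although the list ranked below other genes (p 0.0322, and 0.994 with estimated correlation). For type 2 immunity, mucin glycosylation and the brush border the median change was above 0 while camera gave a lower rank. With RLE the p of the brush border was 0.391, of colon markers 0.183, of type 2 immunity 0.122 and of pancreatic genes 0.0846, and without C57BL/6J mouse 2 the p of type 2 immunity was 0.312 and of the brush border 0.662. Without BALB/cJ mouse 2 it was 0.949 for the brush border and 0.0822 for colon markers. With the B cell score as a covariate, 15 of 77 called ileum genes picked by the naming rules ended, all with a smaller log2 change. For Ltb and Fcer2a, which are members of the score, this follows by construction. The change went from 0.93 to 0.38 for Pdgfra, 0.71 to 0.42 for Kdr and 1.18 to 0.69 for Ccl11. It went from -1.01 to -0.87 for Siglecf, -0.88 to -0.52 for Rnase1 and -0.37 to -0.24 for Cela1. The ileum call of Cbr3, given below, ended too (adjusted p 0.0566).

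**Figure D3:**
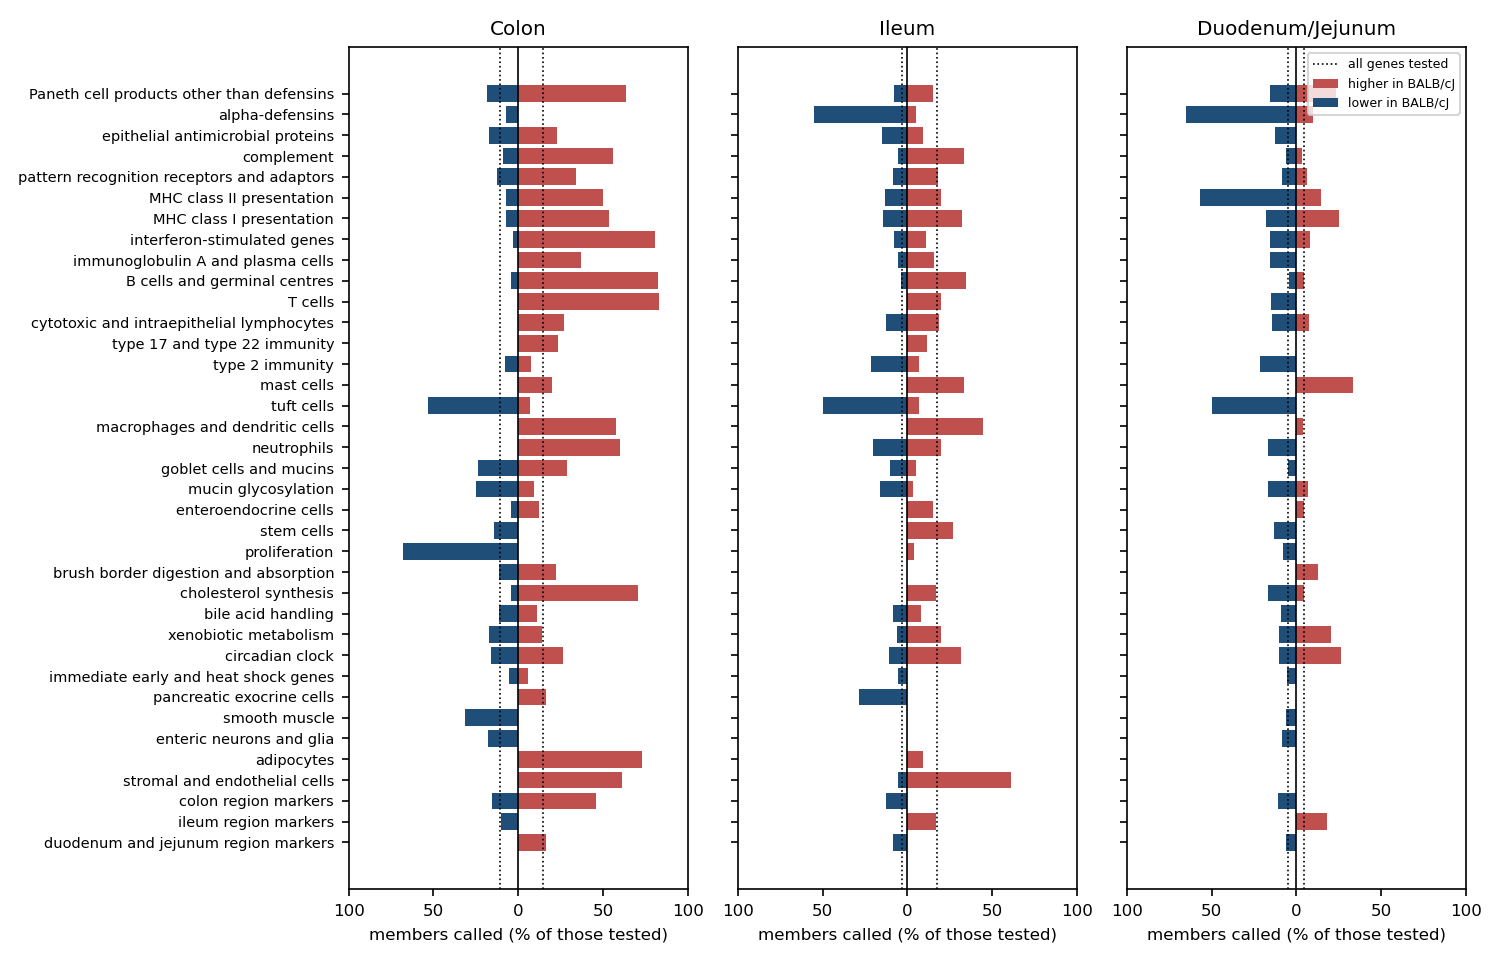
Members of each gene list called higher or lower in BALB/cJ in each tissue, as a percentage of the members tested. Bars are lists and dotted lines are the shares among all genes tested.

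In the duodenum/jejunum, alpha-defensin transcripts were again assigned to different members in each strain. Defa27 was at 4362 ± 1560 TPM in BALB/cJ against 3.40 ± 3.86 in C57BL/6J, and Defa20 at 7.05 ± 1.83 against 5338 ± 1852 (adjusted p 2.6e-09 and 1.6e-13). Defa2, Defa21, Defa22, Defa32 and Defa33 reached 1164, 2203, 1706, 1356 and 280 TPM in C57BL/6J, with at most 3.84 TPM as the mean of any of them in BALB/cJ. Of 20 alpha-defensins 2 were higher, 13 lower and 5 not called (2 and 13 adjusted over the list alone; camera adjusted p 2.0e-14, and p 0.094 with estimated correlation). The sum over Defa genes did not pass (37060 ± 13310 against 45670 ± 10990 TPM, exact permutation p 0.205). Pla2g2a was at 1387 ± 386 against 30.3 ± 7.76 TPM, Mptx1 23.8-fold higher, Mptx2 8.82-fold lower (45.2 ± 16.4 against 399 ± 161) and Ang4, a Paneth cell ribonuclease gene, 3.35-fold lower (113 ± 39.7 against 379 ± 118, adjusted p 0.0001). H2-K2, a class I pseudogene, was 12.7-fold higher, and Eno1b and Rps3a2 were at 273 and 183 TPM against 1.65 and 0.876.

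Limma called 1454 of 15306 genes in the duodenum/jejunum (9.50%), 720 higher and 734 lower in BALB/cJ, with 246 and 229 changed by at least 2-fold. Of all genes tested, 821 were without overlap between strains (0.117% of genes by chance). Without the 3 mice with Y-linked transcripts 927 genes were called. The score of pancreatic genes varied widely between libraries of both strains. Without C57BL/6J mouse 2 it was 3.54 ± 3.09 against 4.55 ± 3.12 on the log2 scale (exact permutation p 0.556). What this spread does to the calls was not tested.

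Immunoglobulin A and most called class II genes were lower in the BALB/cJ duodenum/jejunum. The IgA constant gene Igha was at 1775 ± 755 against 5645 ± 1348 TPM (3.18-fold lower, adjusted p 0.00027; chromosome 12, 113254830 to 113260236) and Xbp1, a plasma cell transcription factor gene, 1.18-fold lower (155 ± 8.79 against 184 ± 9.0, though not called with RLE, adjusted p 0.111). Of 19 plasma cell genes 3 were lower and 16 not called (11 lower and 1 higher adjusted over the list alone; camera adjusted p 0.00013, and p 0.581 with estimated correlation). H2-Ab1 was at 131 ± 22.3 against 427 ± 92.1 TPM, H2-DMb1 2.80-fold and H2-Eb1 1.75-fold lower. Of 14 class II genes 8 were lower, 2 higher and 4 not called (8 and 2 adjusted over the list alone; p 0.0051, and 0.581 with estimated correlation). Their mean score without C57BL/6J mouse 2 was 5.58 ± 0.145 against 5.55 ± 0.149 on the log2 scale (exact permutation p 0.749). Of class I genes, H2-Q2 was 8.78-fold and H2-K1 3.62-fold lower and H2-Q6 3.33-fold higher. Of 28 class I genes 7 were higher, 5 lower and 16 not called (7 and 7 adjusted over the list alone; list p 0.557). The sum over class I genes was 2003 ± 203 against 3120 ± 342 TPM (exact permutation p 0.0012, adjusted 0.011). T cell genes were lower in 3 of 20 with 17 not called (4 adjusted over the list alone), with Cd2 1.84-fold lower (p 0.0209, and 0.581 with estimated correlation, or 0.117 without C57BL/6J mouse 2 and 0.0599 with RLE). The calls of the T cell genes Trac and Cd6 ended without that mouse (limma adjusted p 0.0638 and 0.0543). The call of Igkc (1890 ± 1235 against 4616 ± 1839 TPM, adjusted p 0.0395) ended without that mouse (0.0728), with RLE (0.0679), with the mouse number as a block (0.083) and with the B cell score (0.0593).

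Tuft cell genes were lower here too, with Trpm5 at 2.77 ± 0.913 against 7.79 ± 1.15 TPM, Sh2d6 2.41-fold and Rgs13 1.96-fold lower. Of 14 tested, 7 were lower and 7 not called (10 adjusted over the list alone; camera adjusted p 7.8e-07, and p 0.0841 with estimated correlation). Sprr2a2 was at 29.3 ± 14.2 against 1609 ± 1067 TPM, Sprr2a1 43.1-fold lower, and Nos2 and Duox2 were 5.77-fold and 4.51-fold lower with wide spread in C57BL/6J (31.5 ± 33.1 and 30.9 ± 39.9 TPM). Of 32 antimicrobial genes 4 were lower and 28 not called (8 adjusted over the list alone; p 0.0123, and 0.581 with estimated correlation). St3gal4 was 175-fold lower (6.63 ± 1.81 against 1163 ± 188 TPM), B3gnt3 2.52-fold lower and St3gal6 2.16-fold higher. Of 30 mucin glycosylation genes 2 were higher, 5 lower and 23 not called (2 and 8 adjusted over the list alone; p 0.0179, and 0.581 with estimated correlation). The mast cell protease genes Mcpt1 (13.4 ± 4.85 against 4.04 ± 1.92 TPM) and Mcpt2 were 3.32-fold and 3.80-fold higher.

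Detoxification, absorption and clock genes also differed in the duodenum/jejunum. The glutathione transferase gene Gstm2 was at 202 ± 30.5 against 37.4 ± 10.5 TPM and Cyp3a59 7.63-fold higher, while Gsta1 was 8.06-fold and Gstm3 5.03-fold lower. Of 68 xenobiotic metabolism genes 14 were higher, 7 lower and 47 not called (22 and 11 adjusted over the list alone; camera adjusted p 0.0136, and p 0.748 with estimated correlation). Brush border genes were higher in 4 of 32 with 28 not called (11 adjusted over the list alone), among them Mme at 668 ± 101 against 414 ± 93.4 TPM and Cd36, 1.95-fold higher (p 0.00021, and 0.581 with estimated correlation). The calls of Ace (1.71-fold) and Slc6a20a (1.58-fold) ended without C57BL/6J mouse 2 (adjusted p 0.0559 and 0.0752). Of 19 clock genes 5 were higher, 2 lower and 12 not called (9 and 3 adjusted over the list alone), with Dbp at 66.4 ± 18.2 against 19 ± 15.6 TPM, Per3 2.52-fold higher and Nfil3 2.60-fold and Arntl 1.73-fold lower (p 0.0093, and 0.581 with estimated correlation). The clock genes were not shown to be particular to this tissue, as only 1 of 19 was called for a strain effect that differed between tissues. Without C57BL/6J mouse 2 the clock score was also higher in the ileum (3.69 ± 0.113 against 3.35 ± 0.205, exact permutation p 0.0108), but did not pass in the colon (p 0.193). The labels give no time of collection, so for clock genes strain cannot be told apart from time of day. Of 24 cholesterol synthesis genes 1 was higher, 4 lower and 19 not called (1 and 7 adjusted over the list alone), with Sc5d 1.5-fold and Mvd 1.48-fold lower (p 0.0094, and 0.581 with estimated correlation). Proliferation genes were lower in 2 of 25, Mcm6 by 1.47-fold, with 23 not called (3 adjusted over the list alone; p 0.00013, and 0.581 with estimated correlation). The call of the other, Ccnb2, ended without C57BL/6J mouse 2 (limma adjusted p 0.0569). Of 16 smooth muscle genes Hspb6, 2.06-fold lower, was the only call, with 15 not called (2 adjusted over the list alone; p 0.00084, and 0.605 with estimated correlation), and its adjusted p was 0.0611 without C57BL/6J mouse 2 and 0.0571 with the B cell score. Without that mouse the list p was 0.0663 for antimicrobial genes and 0.0679 for each of mucin glycosylation, xenobiotic metabolism and cholesterol synthesis.

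Some strain differences depended on the tissue. Nxpe5 and Lpo were high in the BALB/cJ colon and near the floor in both strains elsewhere, with ileal means of 1.83 against 1.24 TPM for Nxpe5 and 0.137 against 0.106 for Lpo (adjusted p for a difference between tissues 4.0e-26 and 1.3e-23). Mptx1 was lower in the BALB/cJ colon and higher in both parts of the small intestine (2.7e-19), and Mptx2 the reverse (1.2e-11). The sum of both was lower in BALB/cJ in the colon and in the duodenum/jejunum (119 ± 39.4 against 402 ± 160 TPM, exact permutation p 0.0017, adjusted 0.012). In the ileum it did not pass (268 ± 48.5 against 726 ± 427, p 0.0315, adjusted 0.0539), though without C57BL/6J mouse 2 the exact permutation p was 0.0022. Exchange of reads makes values of the single members less certain than the sum, but an effect of strain variants on the sum was not tested. St3gal4 was lower in all 3 tissues, by 9.77-fold in the colon, 146-fold in the ileum and 175-fold in the duodenum/jejunum (4.5e-18). The carbonyl reductase gene Cbr3 was at 3.90 ± 0.626 against 26.7 ± 4.02 TPM in the colon and 1.98 ± 0.513 against 0.964 ± 0.273 in the ileum (2.0e-15). Gbp2b was higher by 29.1-fold in the colon and 4.26-fold in the ileum (1.0e-13). In the duodenum/jejunum the ratio of its means was 1.42, with overlapping SDs (11.9 ± 3.24 against 8.39 ± 2.64 TPM). Nxpe4 was 32-fold, 3.39-fold and 3.43-fold lower (3.0e-20), and Defa2 differed in the small intestine alone (2.4e-14). Limma called 1577 of 17126 genes for a difference between tissues (9.21%): 698 for ileum against colon, 958 for duodenum/jejunum against colon, and 672 for duodenum/jejunum against ileum, which became 109 with RLE.

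By list, 47 of 64 interferon-stimulated genes differed between tissues in their strain effect (56 adjusted over the list alone), as did 13 of 28 class I presentation genes (17), 9 of 15 class II presentation genes (13), 12 of 24 cholesterol synthesis genes (17) and 12 of 20 alpha-defensins (13). Of 17 tuft cell genes 1 did (1 adjusted over the list alone), and of 25 proliferation genes none (0), so the lower tuft cell genes were not shown to differ between tissues. These counts come from the fit without the mouse as a block, and list counts with that block were not made.

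Some genes kept 1 direction in all tissues. H2-K2 was higher by 6.01-fold in the colon, 14.2-fold in the ileum and 12.7-fold in the duodenum/jejunum, and Actc1, a cardiac-type actin gene, by 14.4-fold, 16.3-fold and 9.02-fold. Chd9, a chromatin remodeller gene, was lower by 14.9-fold, 14-fold and 13.8-fold (98.1 ± 17.4 against 1459 ± 169 TPM in the colon), and Pnp2, a purine salvage gene, by 12.6-fold, 22-fold and 25.9-fold. Of 14622 genes tested in all 3 tissues, 358 were higher in each and 217 lower in each, where independent calls would give 16.7 and 2.16. Ileum and duodenum/jejunum shared 490 higher and 313 lower genes and went opposite ways for 4, colon and ileum shared 1126 and 303 with 45 opposite, and colon and duodenum/jejunum shared 403 and 375 with 55 opposite. The tissues come from the same mice, so differences between these animals count in every tissue.

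**Figure D4:**
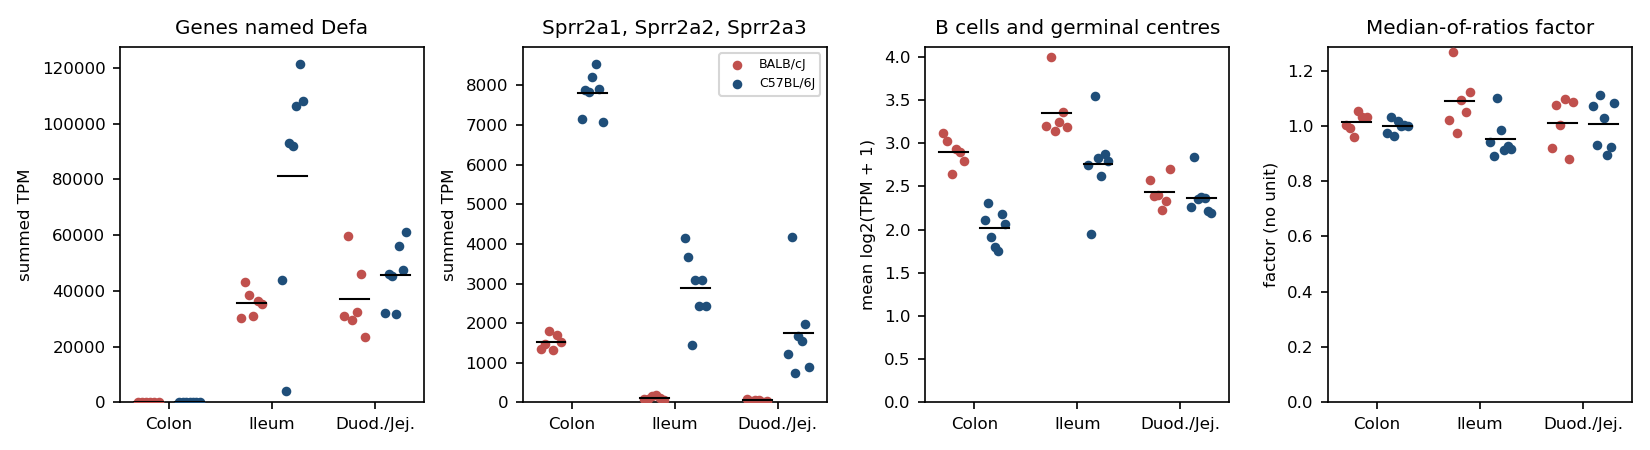
Measures per library by tissue and strain: summed TPM of the Defa and Sprr2a genes, the B cell score and the median-of-ratios factor. Points are libraries and lines are arithmetic means.

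Measures of whole libraries also moved with strain. In the duodenum/jejunum mitochondrial transcripts made up 5.24 ± 0.266% of TPM in BALB/cJ and 4.21 ± 0.583% in C57BL/6J (exact permutation p 0.0052, adjusted 0.021), and the 10 highest genes took 12.8 ± 0.943% against 10.6 ± 0.863% (p 0.0035, adjusted 0.0187). The ileum mitochondrial share was 3.23 ± 0.298% against 3.35 ± 1.99% over all libraries (exact permutation p 0.999), and 2.60 ± 0.238% in C57BL/6J without mouse 2 (exact permutation p 0.00433). In the ileum the 10 highest genes took 9.82 ± 0.353% against 12.7 ± 2.27% (exact permutation p 0.0017, adjusted 0.0076). The Y-linked genes Ddx3y and Eif2s3y stood at 22.4 to 39.2 and 46.6 to 85.6 TPM in the 9 libraries of BALB/cJ mouse 1 and C57BL/6J mice 6 and 7, and at no more than 0.889 and 0.580 TPM in the other 30. Without these 3 mice 1430 genes were called in the ileum.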

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

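Of the tests in this part, those on the libraries of C57BL/6J mouse 2 were chosen after their values were seen. A library was taken to lie far from its group when its gap to the nearest other library, divided by the range of the group, exceeded Dixon's 95% critical value. Of 247 groups of 6 or 7 libraries 33 held such a library, where chance alone gives about 12, and in 21 of them it was a library of C57BL/6J mouse 2.

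In C57BL/6J mouse 2 the library labelled ileum lay apart, with these ratios of gap to range: Pla2g2a 0.682, Defa27 0.702, Defa21 0.765, Defa2 0.791, Defa33 0.831, Defa32 0.814, Defa20 0.774, Defa22 0.753, St3gal4 0.68, Fabp6 0.868, Tmprss15 0.995, the score of ileal markers 0.731, the score of duodenal and jejunal markers 0.572 and the mitochondrial share 0.878. The library labelled duodenum/jejunum of the same mouse lay apart for Fabp6 (0.715), Fgf15 (0.675), Slc51b (0.585), the Sprr2a sum (0.639) and the scores of B cells (0.717), colon markers (0.601) and ileal markers (0.725).

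The labels of these 2 libraries might have been exchanged, but the library labelled duodenum/jejunum kept duodenal and jejunal genes. On a scale from 0, the other C57BL/6J ileum libraries, to 1, the other C57BL/6J duodenum/jejunum libraries, 11 such genes had a median of 0.89 (quartiles 0.333 and 1.1). That median argues against an exchange of labels. The library labelled ileum held the same 11 genes at a median of 0.905, which an exchange alone would also give. The library labelled duodenum/jejunum also held ileal genes at a median of 0.933 of the ileal level over 5 genes (Fabp6 6111 TPM, Slc10a2 86.7, Saa1 359), as ileal tissue within it would give. The library labelled ileum kept 0.00227 of the ileal level over those genes (Fabp6 22.1 TPM, Slc10a2 4.10), so the tables argue against a mixture of ileal and more proximal tissue there. A candidate explanation is that a jejunal and an ileal piece were exchanged before the duodenal and jejunal pieces were joined: across the 11 genes, positions in the 2 libraries were inversely related (Spearman -0.655, Pearson -0.742, one-sided permutation p 0.016 over 100000 resamples, across genes that are not independent). Variation in where each piece was taken was not tested and stays open, and no group of the design bears on a single mouse.

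The other 12 groups with such a library match the number expected by chance, though some libraries recur, namely those of mice 2 and 5 in BALB/cJ ileum and of mouse 1 in BALB/cJ duodenum/jejunum. They were H2-Ea-ps (0.811, mouse 2), Defa20 (0.673, mouse 5), Fabp6 (0.713, mouse 5) and the B cell score (0.748, mouse 2) in BALB/cJ ileum, and Rps3a2 (0.735, mouse 1), Car1 (0.663, mouse 1) and Gkn3 (0.826, mouse 5) in BALB/cJ duodenum/jejunum. In C57BL/6J they were the erythroid score in the colon (0.621, mouse 1), Gvin1 (0.676, mouse 3) and Car1 (0.829, mouse 1) in the ileum, and Actc1 (0.734, mouse 5) and Nxpe4 (0.653, mouse 4) in the duodenum/jejunum. No explanation of these was tested.

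The 28 genes of the label check, of the largest changes and of the rules for differences between and across tissues were looked at for a strain difference that differs between tissues, and 19 passed. As 8 of the genes were picked by their p for this very difference, the count in part restates the choice. Their adjusted p in limma was 3.9e-26 for Nxpe5, 1.3e-23 for Lpo, 3e-20 for Nxpe4, 2.7e-19 for Mptx1, 4.5e-18 for St3gal4, 2e-15 for Cbr3, 2.4e-14 for Defa2, 1e-13 for Gbp2b, 8.7e-12 for Defa27, 1.2e-11 for Mptx2, 1.4e-10 for Defa21, 2.2e-10 for Defa20, 1.3e-09 for Defa33, 8.8e-09 for H2-Ea-ps, 2.5e-08 for Defa22, 2.3e-06 for Defa32, 9.2e-05 for H2-K2, 0.00017 for Pnp2 and 0.0097 for Pla2g2a. Several of these genes are expressed in 1 part of the gut, so a difference between tissues follows in part from where they are expressed.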

How the results depend on the processing

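Settings that leave out mice or a library, that keep protein-coding genes alone or that leave out the alpha-defensins were chosen after the data were seen, as was the joint fit behind the test between tissues. Of the values of named genes under other settings, 337 in the colon, 444 in the ileum and 381 in the duodenum/jejunum were unchanged. These either kept direction and call or were called in neither setting, where direction was not compared. A further 53, 36 and 24 kept direction alone. All 10 that reversed were in the colon with the B cell score as a covariate, which separates the strains there, and none of them was called: log2 changes became -0.18 for Ciita, -0.054 for Ighm, -0.015 for Cd28, -0.015 for Lyz2, 0.28 for Elavl4, -9.2e-05 for Pdgfrb, -0.11 for Kdr, -0.015 for Madcam1, -0.011 for Col3a1 and -0.10 for Zg16.

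Counts of called genes were 3986, 3169 and 1454 in the colon, ileum and duodenum/jejunum. Asking for a 2-fold change as well gave 593, 552 and 475. All 39 libraries in 1 fit, planned for counts alone and run on TPM after the unit was known, gave 2450, 5043 and 2270, and the cause was not tested. The B cell score gave 479 in the colon and 1876 in the ileum. In the ileum RLE gave 1822, the mouse number as a block 926 and TPM rescaled without the alpha-defensins 1693 (1172 higher, 521 lower), and the cause of the block's change was not tested. Within a tissue this block joins different animals that share a number and leaves out C57BL/6J mouse 7, so it has fewer libraries and more terms. Without the 3 mice with Y-linked transcripts, and so with fewer libraries, the ileum gave 1430 and the duodenum/jejunum 927. Other settings stayed within 1.5 times the count.

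Lists called by camera were 17, 12 and 13. With an estimated correlation 0 were called in the colon, 0 in the ileum and 0 in the duodenum/jejunum, and fry called 26, 12 and 11. Of the 42 called by camera over the tissues 17 were not called by fry, among them alpha-defensins (0.0525) and interferon-stimulated genes (0.988) in the ileum. The test between tissues called 1577 genes, 1911 with the mouse as a block, 1128 with RLE, 1880 without the 2 libraries of C57BL/6J mouse 2 and 2436 with both the block and these libraries left out.

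Not run were DESeq2, TMM, total counts and unrounded counts, which need counts, and tests of gene levels between tissues. The test of strain differences between tissues was run. Depth is unknown for TPM, so what it limits could not be assessed.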

Other observations

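Of the tests in this part, those that rescaled TPM without the alpha-defensins, that left out C57BL/6J mouse 2 and that set parent genes, with or without ribosomal protein genes, against genes of like level were chosen after the result was seen.

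Innate sensing genes differed between the strains in every tissue. Ifi202b, an interferon-inducible DNA sensor gene, was at 11.1 ± 1.74, 3.80 ± 0.736 and 2.11 ± 0.692 TPM in BALB/cJ colon, ileum and duodenum/jejunum and at 0.0527, 0.0302 and 0.0204 in C57BL/6J. The inflammasome gene Nlrp1b was 20.7-fold, 11.1-fold and 15.3-fold lower in BALB/cJ, and Pycard, which encodes the inflammasome adaptor, was at 81.0 ± 9.84 against 160 ± 11.1 TPM in the colon and 97.3 ± 30.1 against 201 ± 16.4 in the duodenum/jejunum. In the ileum the lipopolysaccharide receptor gene Tlr4 was 3.23-fold and Tlr6 3.06-fold higher, and in the duodenum/jejunum the co-receptor gene Ly96 was 2.40-fold lower. Of the pattern recognition genes 16 of 47 were higher and 6 lower in the colon, 9 and 4 of 49 in the ileum and 3 and 4 of 47 in the duodenum/jejunum, and camera called the list in none of the tissues (adjusted p 0.283, 0.984 and 0.259).

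For the number of genes called, chance in how the mice were grouped can be excluded: of 100 splits of the 13 libraries of a tissue into 6 and 7, the real one included, 1 called as many in the colon (3986, highest other 4), 1 in the ileum (3169, highest other 639) and 1 in the duodenum/jejunum (1454, highest other 1), and 1 of 100 for the difference between tissues (1577, highest other 12). The splits do not bear on handling that went with strain. Sample titles number all BALB/cJ libraries before all C57BL/6J libraries, so an effect of handling order cannot be told apart from strain. For the number of lists chance cannot be excluded: 9 of 100 splits called as many lists in the colon (17, highest other 21), 66 in the ileum (12, highest other 19) and 51 in the duodenum/jejunum (13, highest other 25). Members of a list vary together between mice, so the list tests with a preset correlation call lists under most splits. Counts of called members per list were not put through the splits, and members that vary together can also be called together.

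Most ileum calls were higher in BALB/cJ, and abundant transcripts of C57BL/6J could take up part of each library. With all Defa genes left out and TPM rescaled, the median log2 change of all genes was 0.104 in place of 0.17, and with the 100 most abundant genes left out, which held 29.1 ± 0.941% of TPM in BALB/cJ and 34.2 ± 2.11% in C57BL/6J, it was 0.0683. Each removes part of the shift and neither value lies where it would decide, so these explanations cannot be told apart from a difference in the other genes. The tables argue against C57BL/6J mouse 2 as the cause, since 83.4% of calls were higher without it. With the B cell score as a covariate the median was 0.0496 and 69.8% of 1876 calls were higher. The score itself is higher in BALB/cJ ileum (3.36 ± 0.325 against 2.77 ± 0.468, exact permutation p 0.0181, adjusted 0.0413), so it shares its effect with strain. A difference in cell composition between the strains stays open.

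Processed pseudogenes, intronless copies of other genes, were called by at least 2-fold in 1 direction in every tissue far more often than protein-coding genes, 61 higher and 7 lower of 691 (9.84%) against 56 and 41 of 13062 (0.743%). Reads of a parent gene may be assigned to its copy in 1 strain: 65 of the 68 copies shared sequence with a parent, which moved in the opposite direction in 69.2% of pairs, against a median of 52.3% and a 95th percentile of 61.5% when genes of like level stood in for the parents (permutation p 0.0034). This rests in part on ribosomal protein genes, with 14 of 15 pairs opposite, and on parents that recur, 1 of them in 5 pairs. A parent was the tested protein-coding gene that shared the most stretches of 31 bases with the copy, at least 20. Some matches were thin, as for Gm17764 with Mrps14 (21 of 361) and Ywhaq-ps1 with Sfn (42 of 680), so some parents may be wrong. The heat shock chaperone gene Hspa8, parent of 2 copies, was 1.85-fold, 1.67-fold and 2.14-fold lower (limma adjusted p 0.00025, 0.0064 and 0.00019). In the other 50 pairs, with 1 drawn gene per parent, 62% were opposite against a median of 52% and a 95th percentile of 64% (permutation p 0.122), which cannot decide. Reshuffling the pairs gave a median of 69.2% as well, which had been set beforehand to count against this, but 59 of these copies are higher and 6 lower, so reshuffling hardly changes the signs and that bound was wrong. A strain difference of the chromosome region around the copy is argued against, as 4.41% of copies lay within 500 kb of a protein-coding gene called in the same way, where random sets of processed pseudogenes had a median of 5.88% and a 95th percentile of 11.8%. Variants of BALB/cJ against the C57BL/6J reference, or copies present in 1 strain, were not tested and stay open.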
